A study of Arabidopsis thaliana with 14 samples.

How the data were processed

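Transcript levels were measured in 14 RNA samples of Arabidopsis thaliana, Columbia ecotype, each on a separate single-colour Agilent array (Cy3). Per the labels' protocols, plants grew in a greenhouse with 16 h of light and 8 h of dark at 22 °C, and total RNA was extracted with Trizol, cleaned on RNeasy columns, and labelled from 2 µg. Whole flower buds before floral stage 8 came from wild type, from the double mutant of the RING finger genes RING1A and RING1B (ring1ab), from lhp1 and from clf, with 2 arrays per genotype. The bud stage is that of the labels and was not checked. Seedlings 7 days old came from wild type and ring1ab, with 3 arrays per genotype. The series design describes the replicates as grown and harvested independently, with 1 array each.

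The deposited scanner files hold spot intensity values written by Agilent Feature Extraction 10.5.1.1, per the file headers, which also give the grid build as ath1:Jan2004. The processed signal in these files is an intensity after the software's background handling, per the file headers, and is not normalized between arrays. The authors' series table holds log2 values of the same arrays: its columns correlated with log2 of the processed signal of their own arrays at r between 0.997 and 1 across probes. The sorted values were the same within 11 of these columns to their printed decimals, which marks quantile normalization, while ring1ab buds replicate 1 and ring1ab seedlings replicate 2 shared another set. The column medians were 9.909 in those 2 columns and 9.904 in the other 12. No centring of genes was found in this table, and the table gives levels, so no direction had to be assumed. How the authors produced it is otherwise not given in the sources used here.

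For the main results, control spots and spots flagged as non-uniform or population outliers were left out (12 to 41 of 43803 non-control spots per array). Spots of a probe were averaged, and the 75th percentile of the array was subtracted from log2 of the processed signal. All levels below are on this log2 scale. Loci were taken from accessions and names in the scanner files: of 43603 probes, 34039 were assigned by accession, 2022 by gene name and 63 by description, 437 matched several loci, and 7042 none. This gave 26448 loci, of which 26184 had an entry in the reference table (assembly TAIR10.1). That table was used only for symbols and for which genes neighbour each other, since its build differs from that in the headers. A locus was represented by its probe with the highest mean over the 14 arrays; 7475 loci had more than 1 probe. Of the called genes with several probes, 14 of 1438 in ring1ab buds, 0 of 84 in lhp1 buds, 0 of 0 in clf buds and 3 of 226 in ring1ab seedlings had a probe that moved the opposite way by over 0.5 on the log2 scale.

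A locus was tested in a fit if any of its probes was well above background on every array of at least 1 group of that fit. Differences were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, p-values were adjusted by the Benjamini-Hochberg method over the tested genes, and a gene was called at an adjusted p under 0.05. The 8 bud arrays shared 1 fit (4 residual degrees of freedom), and the 6 seedling arrays another (4 residual degrees of freedom). The difference of the ring1ab effect between tissues and the difference between wild-type tissues used all 14 arrays (8 residual degrees of freedom). The errors printed beside log2 changes are the standard errors of limma after moderation. Where a gene was not well above background on any array of a group, its fold is given as "at least N-fold": the brighter group's mean against the dimmer group's mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for reading, tables and plots.

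The lists of genes were fixed before the data were examined, as were the design, the rule for named genes and the first set of alternatives. They are PRC1 components, PRC2 components, class I KNOX, boundary and shoot meristem, floral organ identity, flowering time, embryo regulators, seed storage and maturation, WOX homeobox family, root apex regulators, root hair, leaf polarity and TCP, carpel and ovule, anther and tapetum, mature pollen, meiosis, photosynthesis, cell cycle and replication, auxin biosynthesis, heat shock, defence, jasmonate and wounding, and reference genes. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, over the members with values on every array (5 of the 6 tested defence genes in buds, all tested members otherwise), adjusted over the lists of a comparison, and again with the correlation estimated from the data. Counts of members called are given over all genes tested and, where they differ, adjusted over the list alone. Named genes were the 4 mutated genes, the 4 class I KNOX genes, the 6 largest called rises and the 6 largest called falls with a symbol and with groups that did not overlap, and up to 3 called members of each list with the smallest adjusted p. Where fewer than 6 were called, places were filled by the largest moderated statistic and the text says that these did not pass. For differences between mutants and between tissues, the 3 largest in each direction were taken by the same rule.

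Comparisons against the same wild-type bud arrays share chance values, so 100 draws of unchanged groups against those arrays were simulated. The overlap of independent lists was computed beside them. The method was also tested on simulated data with known changes. Of 100 genes given a 2-fold change it recovered 27% in ring1ab buds, 25% in lhp1 buds, 36% in clf buds (21336 genes each) and 83% in ring1ab seedlings (18944 genes). Of 100 genes given a 4-fold change it recovered 83%, 80%, 80% and 98% in the same order. False calls numbered 5, 8, 6 and 16. With so few changed genes these shares need not hold where many genes change, as in ring1ab buds.

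Replicates of a group never held identical values. The alternatives were quantile normalization, normexp background correction with quantile normalization (offset 50), the authors' values, no filter and a stricter filter on dim probes, the mean of a gene's probes, a fit of only the groups compared, 1 fit of all 14 arrays, an intensity trend, array weights, the slide as a random or fixed block, the replicate number as a block, a minimum change of 2-fold, the estimated correlation for lists, and leaving out each array in turn. A fit without 2 bud arrays whose mutated genes differed from those of their replicates, the scan session as a block, and a different wild-type array for each mutant in the covariance of bud mutants were added after seeing the data. The replicate numbers did not pair the seedling samples, and a weak pairing in buds stays open. The arrays lay on 5 slides and were scanned in 2 sessions: the second session held ring1ab buds replicate 1 and ring1ab seedlings replicate 2. Slide 4 held only ring1ab buds replicate 1, and slide 5 only ring1ab seedlings replicate 2. With the slide as a fixed block these arrays do not enter the group effects. The ring1ab bud effect then rests on the library labelled replicate 2. Probes without a locus were left out of the comparisons between groups. The precision is limited by the number of arrays.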

Results

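Transcript levels were compared between wild-type Arabidopsis and mutants of the Polycomb group, proteins that keep developmental genes silent through chromatin. RING1A and RING1B are the RING finger components of Polycomb repressive complex 1 (PRC1), LHP1 binds the histone mark set by Polycomb repressive complex 2 (PRC2), and CLF is a histone methyltransferase of PRC2. The data comprised 8 arrays of young flower buds (wild type, ring1ab, lhp1 and clf, n = 2 each) and 6 arrays of seedlings (wild type and ring1ab, n = 3 each). Each array held 43803 non-control spots, none of them saturated. Between 65.1% (ring1ab seedlings replicate 1) and 73.7% (wild-type buds replicate 2) of these were well above background, and the 75th percentile of the processed signal ranged from 3871 to 7951 intensity units. Levels are log2 processed signal minus the array's 75th percentile, and adjusted p-values are from limma.

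The mutated genes were examined first, as a check of the labels. CLF (probe on chromosome 2, 9967123 to 9967182, plus strand, in the build of the file headers, ath1:Jan2004) was not well above background on either clf array, at -7.93 and -8.09. It lay at -0.84 and -1.84 in wild-type buds, so it was at least 24.2-fold lower in clf (adjusted p = 0.0178). LHP1 (chromosome 5, 5827506 to 5827653, minus strand) was not above background in lhp1 buds replicate 2, at -8.43, but lay at -2.12 on the array labelled lhp1 buds replicate 1, against 0.11 and 0.03 in wild type. RING1B (chromosome 1, 947220 to 947279, plus strand) was not above background in ring1ab buds replicate 1, at -8.38, but lay at -3.24 on the array labelled ring1ab buds replicate 2, against -1.63 and -1.57 in wild type. The library labelled lhp1 buds replicate 1 therefore goes against its label in part, and the library labelled ring1ab buds replicate 2 differs from its replicate. With both included, neither LHP1 in lhp1 buds (log2 change -5.35 ± 1.85, adjusted p = 0.172) nor RING1B in ring1ab buds (-4.21 ± 1.5, adjusted p = 0.0913) passed the test. Without both, in a fit added after seeing the data, LHP1 (adjusted p = 0.00484) and RING1B (adjusted p = 0.000346) were called lower. The mutant arm was then 1 array without signal above background for the gene, so the sizes of these falls are set by the background.

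The signal of RING1A (chromosome 5, 17853345 to 17853505, minus strand) was higher in ring1ab, not lower. It lay at 0.45 and 0.21 in ring1ab buds and at -2.62 and -2.71 in wild-type buds, a log2 change of 2.99 ± 0.43 (adjusted p = 0.0113). In ring1ab seedlings it lay at 4.86, 4.59 and 4.79, against -2.94, -3.14 and -2.51 in wild type (log2 change 7.61 ± 0.18, adjusted p = 2.06e-06). Where the mutation lies relative to this probe is not given in the sources used here, so the probe does not check the label. RING1B in ring1ab seedlings was above background at -3.96, -3.95 and -4.78, and fell by 2.05 on the log2 scale (± 0.24, adjusted p = 0.00455). Its probe thus kept a signal on all 3 ring1ab seedling arrays, as on the array labelled ring1ab buds replicate 2, so a remaining RING1B signal does not by itself put a ring1ab label in doubt, and neither probe establishes the genotype of the seedlings.

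**Figure D1:**
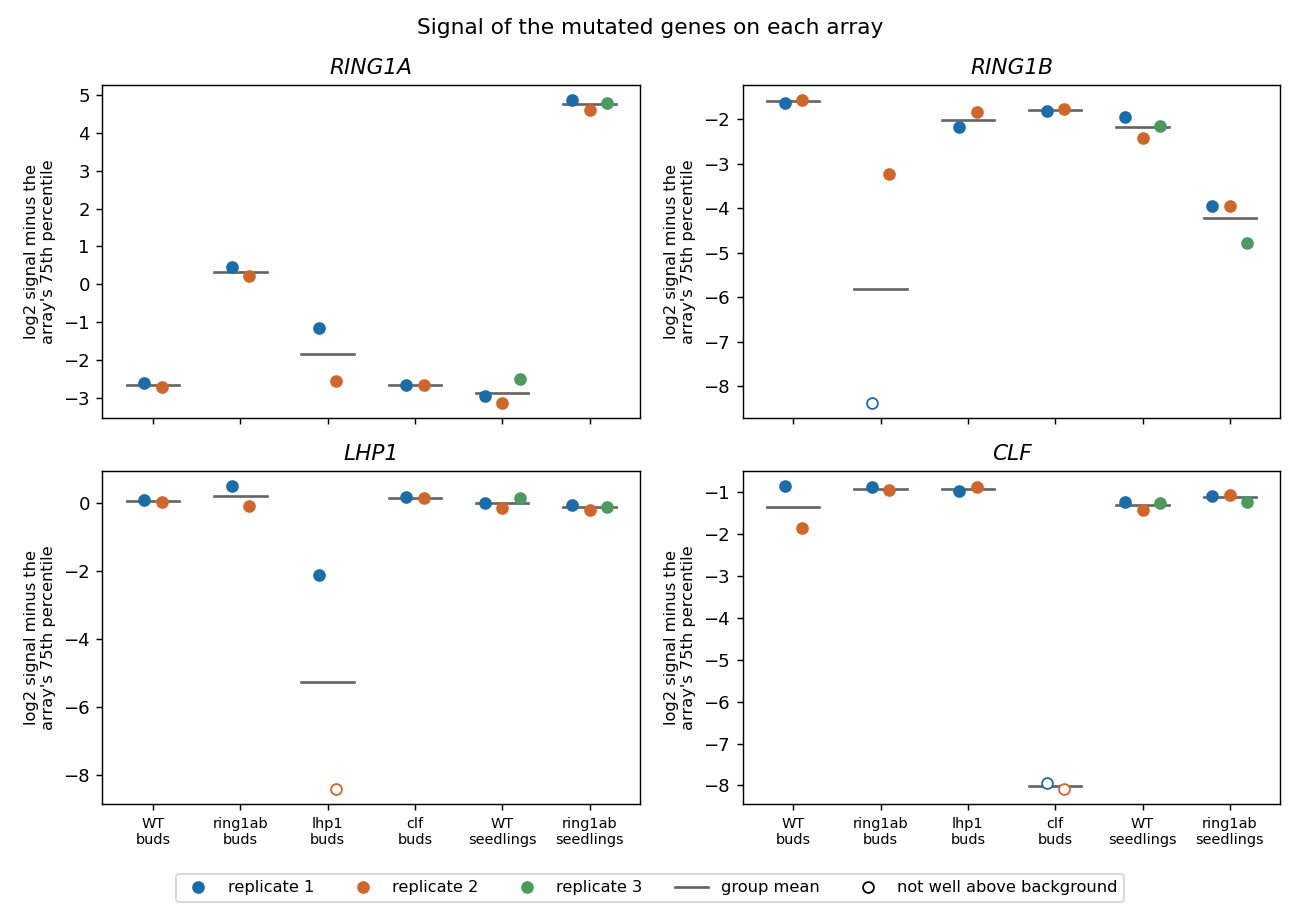
Log2 signal of RING1A, RING1B, LHP1 and CLF on each of the 14 arrays, minus the array's 75th percentile; points are single arrays, coloured by replicate number, open where the gene was not well above background, and bars are group means. LHP1 lies at -2.12 and -8.43 on the lhp1 arrays, and RING1B at -8.38 and -3.24 on the ring1ab bud arrays.

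The same 2 libraries stood apart across other genes. There were 44 genes above background on both ring1ab bud arrays, at a level over -2 in replicate 1, and on no array of wild-type, clf or lhp1 replicate 2 buds, a set chosen after seeing the data. Of these, 43 were above background on the array labelled lhp1 buds replicate 1, with a median log2 difference of -1.82 from the array labelled ring1ab buds replicate 2 (quartiles -1.90 and -1.75).

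**Figure D2:**
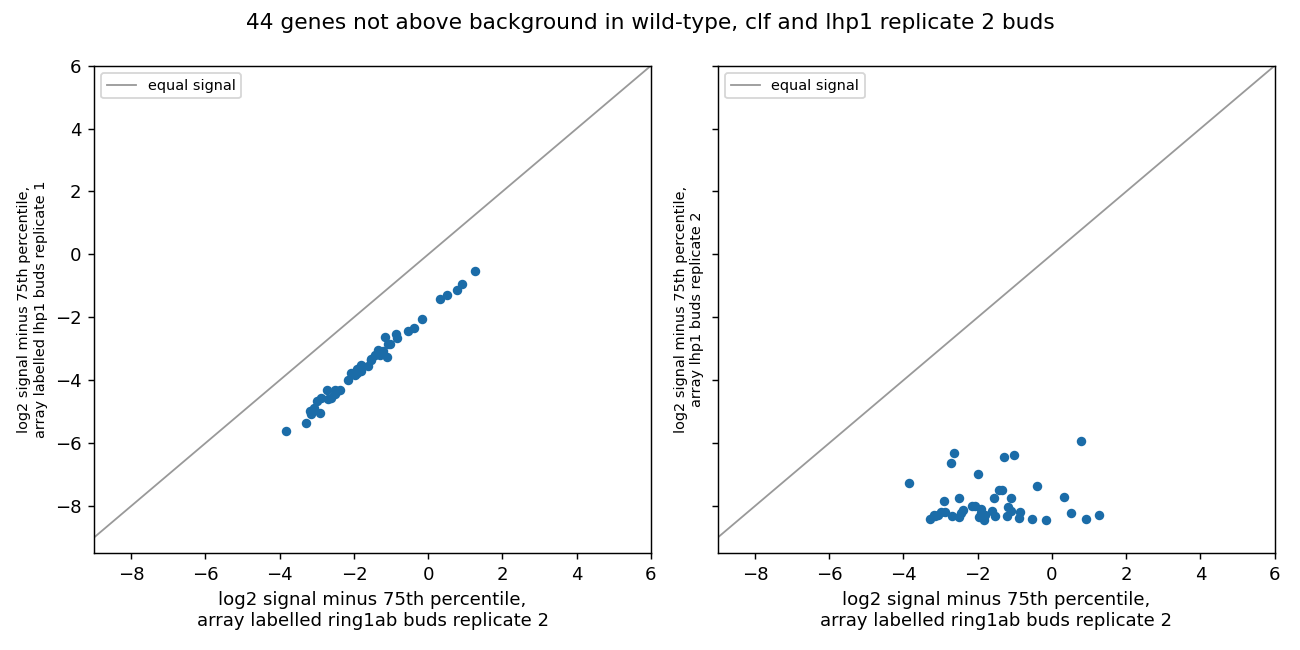
Log2 signal (minus the array's 75th percentile) of these 44 genes on the array labelled lhp1 buds replicate 1 (left) and on lhp1 buds replicate 2 (right), against the array labelled ring1ab buds replicate 2; points are genes and the line marks equal signal. On the left the points run parallel to the line at a median distance of -1.82, and on the right none is above background.

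The comparison of ring1ab with wild-type buds asks which transcripts depend on the RING1 proteins in the young flower. The largest rises included genes of seed maturation. PER1, a peroxiredoxin of the seed, was at least 107-fold higher (log2 change 9.0 ± 1.93, adjusted p = 0.0255). The late embryogenesis abundant genes EM6 and AtLEA4-1 were at least 97.5-fold and 149-fold higher, and EM1 rose by a log2 change of 8.35 ± 2.31 (adjusted p = 0.0485). ABI3, the transcription factor of seed maturation, was at least 67.5-fold higher, and PKR2, which encodes a chromatin remodelling factor related to PICKLE, rose by a log2 change of 7.87 ± 1.64. The largest falls were in FLA14 (an arabinogalactan protein, -5.51 ± 1.22), PPC4 (a phosphoenolpyruvate carboxylase, -5.48), the cysteine-rich genes LCR33 (-5.36), LCR34 (-5.36) and SCRL22 (-5.15), and SULTR3;5 (-5.28). Each of these 6 was above background on only 1 of the 2 ring1ab arrays, the one labelled replicate 2.

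By list, 9 of the 11 tested seed storage and maturation genes rose and none fell (mean log2 change 4.88, adjusted p = 0.00109, and adjusted p = 0.522 with an estimated correlation). Of the 11, 6 were above background on no wild-type bud array, so the size of this mean rests in part on the background. The risers included PAP85, a vicilin-like storage protein (6.80 ± 1.01), the oil body protein OLEO1 (at least 14.8-fold higher) and the cruciferin CRU2 (at least 2.29-fold higher). Of the 4 class I KNOX genes, which maintain the shoot meristem, KNAT2 (1.29 ± 0.20), KNAT6 (1.08 ± 0.23) and KNAT1 (0.84 ± 0.23) rose, while STM lay at a log2 change of 0.99 ± 0.34 (adjusted p = 0.0820) and was called when adjusted over the list alone. The KNOX list shifted upwards (mean 1.05, adjusted p = 0.0338, and adjusted p = 0.522 with an estimated correlation). This call was lost without the 2 doubtful arrays (mean 1.31, adjusted p = 0.0589), without wild-type buds replicate 1 (0.84, 0.0510), with the replicate block (1.05, 0.0534), with the authors' values (1.3, 0.0539) and with only the groups compared (1.05, 0.0511). Of 19 anther and tapetum genes 6 fell, among them QRT3, a polygalacturonase needed for pollen separation (-2.12 ± 0.17), LTP12 (-1.76 ± 0.24) and SPL (-1.06 ± 0.16). The list's mean was -0.83 (adjusted p = 0.00109, and adjusted p = 0.522 with an estimated correlation). Of 5 mature pollen genes 4 fell (mean -3.10, adjusted p = 0.0242, and adjusted p = 0.522 with an estimated correlation). The list's mean was -4.14 on ring1ab buds replicate 1 and -2.06 on the array labelled replicate 2. With the stricter filter on dim probes its call was lost at a similar mean (-3.06, adjusted p = 0.0694). The pollen actin ACT4 was at least 4.52-fold lower, and ACT12 (-3.11 ± 0.72) and the pectin methylesterase VGD1 (-4.24 ± 1.15) fell as well.

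The remaining lists did not pass as sets in the main fit of ring1ab buds, though single members did. With the slide as a fixed block, where the ring1ab effect rests on the library labelled replicate 2, boundary and shoot meristem, photosynthesis, and cell cycle and replication passed. Their mean log2 changes were then 1.07, 0.64 and 0.82. With no filter on dim probes the meiosis list passed (adjusted p = 0.0484). These lists also crossed the threshold when single bud arrays were left out. Without wild-type buds replicate 2 the means of boundary and shoot meristem, meiosis and photosynthesis were 0.78, -0.87 and 0.51. With all arrays they were 0.67, -0.65 and 0.25. The cell cycle and replication mean was 0.35 without wild-type buds replicate 1 and 0.27 without ring1ab buds replicate 1, against 0.28. Of 10 boundary and shoot meristem genes 5 rose and 2 fell (6 and 2 adjusted over the list alone, adjusted p = 0.121). The organ boundary genes CUC1 (2.47 ± 0.34) and CUC2 (1.76 ± 0.30) rose and BOP1 (-0.86 ± 0.15) fell. Of 21 flowering time genes 7 rose and 2 fell (7 and 3 adjusted over the list alone, adjusted p = 0.416), with AGL24 (3.56 ± 0.36) and TFL1 (3.09 ± 0.52) higher and TSF (at least 1.0-fold) lower. Among 14 floral organ identity genes CAL (1.18 ± 0.15) rose, and the stamen and carpel genes AP3 (-0.73 ± 0.14) and AG (-1.0 ± 0.26) fell. In that list 2 rose and 2 fell, or 4 and 5 adjusted over the list alone (adjusted p = 0.788). Of 6 embryo regulators 3 rose, including DOG1 (at least 7.29-fold) and WOX2 (at least 2.98-fold), and FUS3 fell (-3.65 ± 0.92, adjusted p = 0.151 for the list). Of 11 WOX genes 3 rose and 1 fell (adjusted p = 0.212): WOX5, a gene of the root stem cell niche, was at least 5.95-fold higher and WOX12 rose by 2.22 ± 0.31. WOX5 was also the riser among 3 root apex regulators (2 adjusted over the list alone, adjusted p = 0.121), and COBL9, the single tested root hair gene, fell (-3.18 ± 0.54).

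Of 11 carpel and ovule genes 6 rose and 2 fell (6 and 3 adjusted over the list alone, adjusted p = 0.272), led by SPT (1.30 ± 0.19), CRABS CLAW (CRC, AT1G69180, 1.19 ± 0.20) and ALC (0.79 ± 0.15). Among 14 leaf polarity and TCP genes ETT (0.70 ± 0.13) rose and TCP3 (-1.09 ± 0.15) and TCP4 (-0.89 ± 0.17) fell, and adjusted over the list alone 2 rose and 3 fell (adjusted p = 0.951). Of 7 auxin biosynthesis genes 2 rose and 3 fell (adjusted p = 0.788), with YUC1 (2.17 ± 0.30) and YUC4 (1.28 ± 0.23) higher and YUC2 (-1.30 ± 0.18) lower. The meiotic cohesin SYN1 (-2.43 ± 0.28) and MMD1 (at least 1.97-fold lower) were the 2 of 11 meiosis genes that fell (adjusted p = 0.0884). Of 13 cell cycle and replication genes, CYCD3;1 (0.87 ± 0.13) and KN (0.67 ± 0.12) rose (adjusted p = 0.0621). Of 6 defence genes 3 rose (4 adjusted over the list alone), namely PR2 (at least 11.2-fold), WRKY70 (1.30 ± 0.26) and PAD4 (1.13 ± 0.27). The adjusted p of that list was 0.0621, and 0.522 with an estimated correlation. The defence list passed with normexp (0.0414), no filter (0.0473), array weights (0.0469) and the slide as a random (0.0383) or fixed (0.0174) block, and without wild-type buds replicate 1 (0.0439) or 2 (0.0346) or ring1ab buds replicate 1 (0.00868). Of 4 heat shock genes HSP18.2 (1.38 ± 0.25) rose and HSP90.1 (-0.71 ± 0.17) fell (2 fell adjusted over the list alone, adjusted p = 0.795). Of 6 PRC1 components RING1A and BMI1A (0.47 ± 0.13) rose (adjusted p = 0.20). CLF (0.43 ± 0.31) and LHP1 (0.14 ± 1.85) did not pass. No member passed among 7 PRC2 components (adjusted p = 0.934), 21 photosynthesis genes (0.20), 6 jasmonate and wounding genes (0.101) and 6 reference genes (0.977). The mean, the median and the test differed in sign for PRC1 components, leaf polarity and TCP, heat shock, and reference genes.

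In all, 5230 of 21351 tested genes differed between ring1ab and wild-type buds, 2358 higher and 2872 lower. The count rests on single arrays: it was 463 without wild-type buds replicate 1, 1804 without wild-type buds replicate 2, 2529 and 2567 without clf buds replicate 1 and 2, and 8143 without the library labelled ring1ab buds replicate 2. Without both doubtful libraries it was 8353, holding 4704 of the 5230, and BMI1A, PAD4, KNAT1, DOG1 and HSP90.1 were no longer called while STM was. No slide held both a mutant and the wild type of the same tissue, so no within-slide value can be had; with the slide as a fixed block in a fit of all 14 arrays the count was 191, and within the first scan session (without ring1ab buds replicate 1) it was 3565. The balance of directions moved too: 45.1% of the calls were higher, but 64.7% of 337 with only the groups compared and 22.0% of the 191 with the slide block. With that slide block ring1ab buds replicate 1, alone on slide 4, did not enter the ring1ab effect. The slide fit in ring1ab buds therefore rests on the library labelled replicate 2 and cannot test the slide of replicate 1. The mean log2 change of the list seed storage and maturation was 4.54 in that fit, and that of the anther and tapetum list -0.43.

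**Figure D3:**
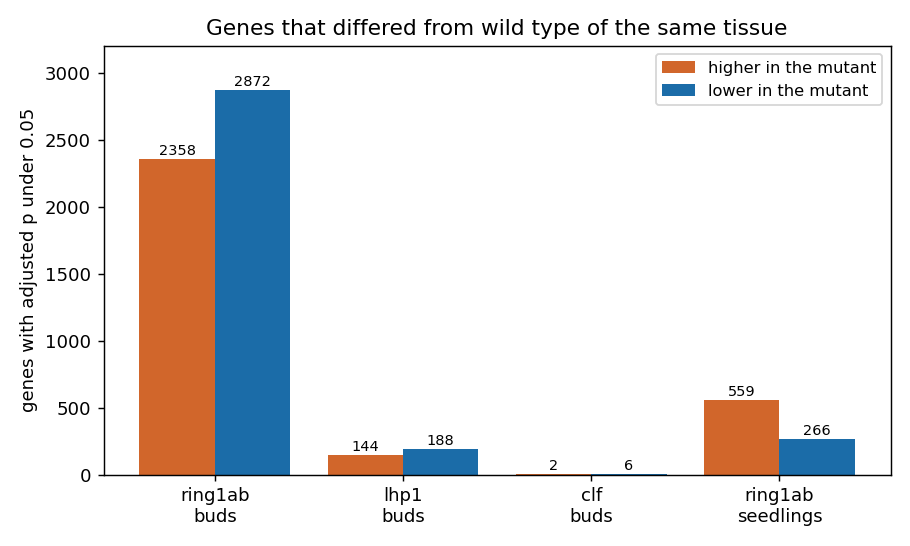
Number of genes with an adjusted p under 0.05 that were higher or lower than in wild type of the same tissue, for the 4 main comparisons. The bars give 2358 and 2872 genes in ring1ab buds, 144 and 188 in lhp1 buds, 2 and 6 in clf buds, and 559 and 266 in ring1ab seedlings.

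The comparison of lhp1 with wild-type buds asks the same of LHP1. Among the largest rises, FSD1, an iron superoxide dismutase, rose by a log2 change of 7.09 ± 0.61 (adjusted p = 0.0197), the glutathione S-transferase GSTF2 by 4.83 ± 0.23 (adjusted p = 0.00639), the chitinase CHI by 4.58 ± 0.41 and the tyrosine aminotransferase TAT3 by 4.52 ± 0.60. PR2, a pathogenesis-related glucanase, was at least 35.9-fold higher and the transporter gene UMAMIT36 at least 5.20-fold. The largest falls were in PRSL1 (at least 1.43-fold), SP1L5 (-2.29 ± 0.18), QQS (-2.19 ± 0.23), SCRL21 (at least 1.15-fold), the flowering gene TSF (at least 1.01-fold) and PGP10 (at least 1.18-fold).

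Of the 21 photosynthesis genes none passed over all genes, but 15 rose adjusted over the list alone, and the list shifted upwards (mean 0.73, adjusted p = 3.11e-08, and adjusted p = 0.831 with an estimated correlation). The mean log2 change of the list photosynthesis in lhp1 buds was 0.47 without wild-type buds replicate 1 (adjusted p = 3.32e-06) and 0.99 without replicate 2 (adjusted p = 1.89e-11), so its size rests on 2 differing controls. Of 6 defence genes PR2 rose (4 adjusted over the list alone), with an adjusted p of 5.46e-04 for the 5 members with values on every array and 0.376 with an estimated correlation. With the stricter filter on dim probes the list kept 3 members and its call was lost (mean 0.80, against 2.62 in the 5, adjusted p = 0.0869). Of 19 anther and tapetum genes QRT3 (-1.19 ± 0.17) fell and 13 fell adjusted over the list alone (mean -0.74, adjusted p = 1.05e-06, and adjusted p = 0.831 with an estimated correlation). No meiosis gene passed over all 11, 1 fell adjusted over the list alone, and the list lay lower (mean -0.61, adjusted p = 0.0365, and adjusted p = 0.90 with an estimated correlation). The meiosis list was no longer called without wild-type buds replicate 1 (mean -0.38) or ring1ab buds replicate 1 (-0.61). Its call was also lost without the library labelled ring1ab buds replicate 2 (-0.61), that labelled lhp1 buds replicate 1 (-0.55), or both (-0.55). At a similar mean it was lost with quantile normalization (-0.59, adjusted p = 0.0802) and only the groups compared (-0.61, 0.0799). The same held for the slide as a random block (-0.63, 0.0581) and the scan session as a block (-0.61, 0.0520). At a smaller mean it was lost with normexp (-0.35, 0.0771), the stricter filter (-0.33, 0.275) and the slide as a fixed block (-0.28, 0.550). Of 5 mature pollen genes ACT4 (-1.59 ± 0.20) fell (mean -1.16, adjusted p = 0.0664 for the list, and 0.831 with an estimated correlation). That list passed in other fits, among them those without the filter (0.0324), with only the groups compared (0.00312), with normexp (0.0492), array weights (0.0397), 1 fit of all 14 arrays (0.0290) or the scan session as a block (0.0192), and without both doubtful libraries (0.0140). Adjusted over the list alone, 1 of 10 boundary and shoot meristem and 1 of 14 leaf polarity and TCP genes fell, 1 of 21 flowering time genes rose and 1 fell, and 1 of 4 heat shock genes rose and 2 fell. The KNOX genes did not pass, with log2 changes of 0.34 (KNAT2), 0.21 (KNAT6), 0.01 (KNAT1) and -0.11 (STM), and neither did RING1A (0.81), CLF (0.42) or RING1B (-0.41). None of 11 seed storage and maturation genes passed, and the list did not (mean 1.64, adjusted p = 0.134). It passed with the slide as a fixed block (mean 1.73, adjusted p = 0.0461). The mean of that list was 3.02 on the array labelled lhp1 buds replicate 1 and 0.25 on lhp1 buds replicate 2. Mean, median and test differed in sign for PRC1 components, flowering time and auxin biosynthesis.

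In all, 332 of 21351 genes differed in lhp1 buds, 144 higher and 188 lower. Leaving out 1 array moved this count over 1.5 times for 7 of the 8 bud arrays: to 0 without wild-type buds replicate 1, 2532 and 2480 without ring1ab buds replicate 1 and the library labelled replicate 2, 123 and 12 without the library labelled lhp1 buds replicate 1 and replicate 2, and 3 without either clf array. Without both doubtful libraries it was 1643, holding 270 of the 332 and no longer TAT3. The balance of directions depends on the fit: 43.4% of the calls were higher, but 63.3% with the intensity trend, 58.0% of 50 calls with the slide as a random block, 54.8% without the filter, 52.9% with the replicate block, 51.5% in 1 fit of all 14 arrays and 50% with the scan session as a block.

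**Figure D4:**
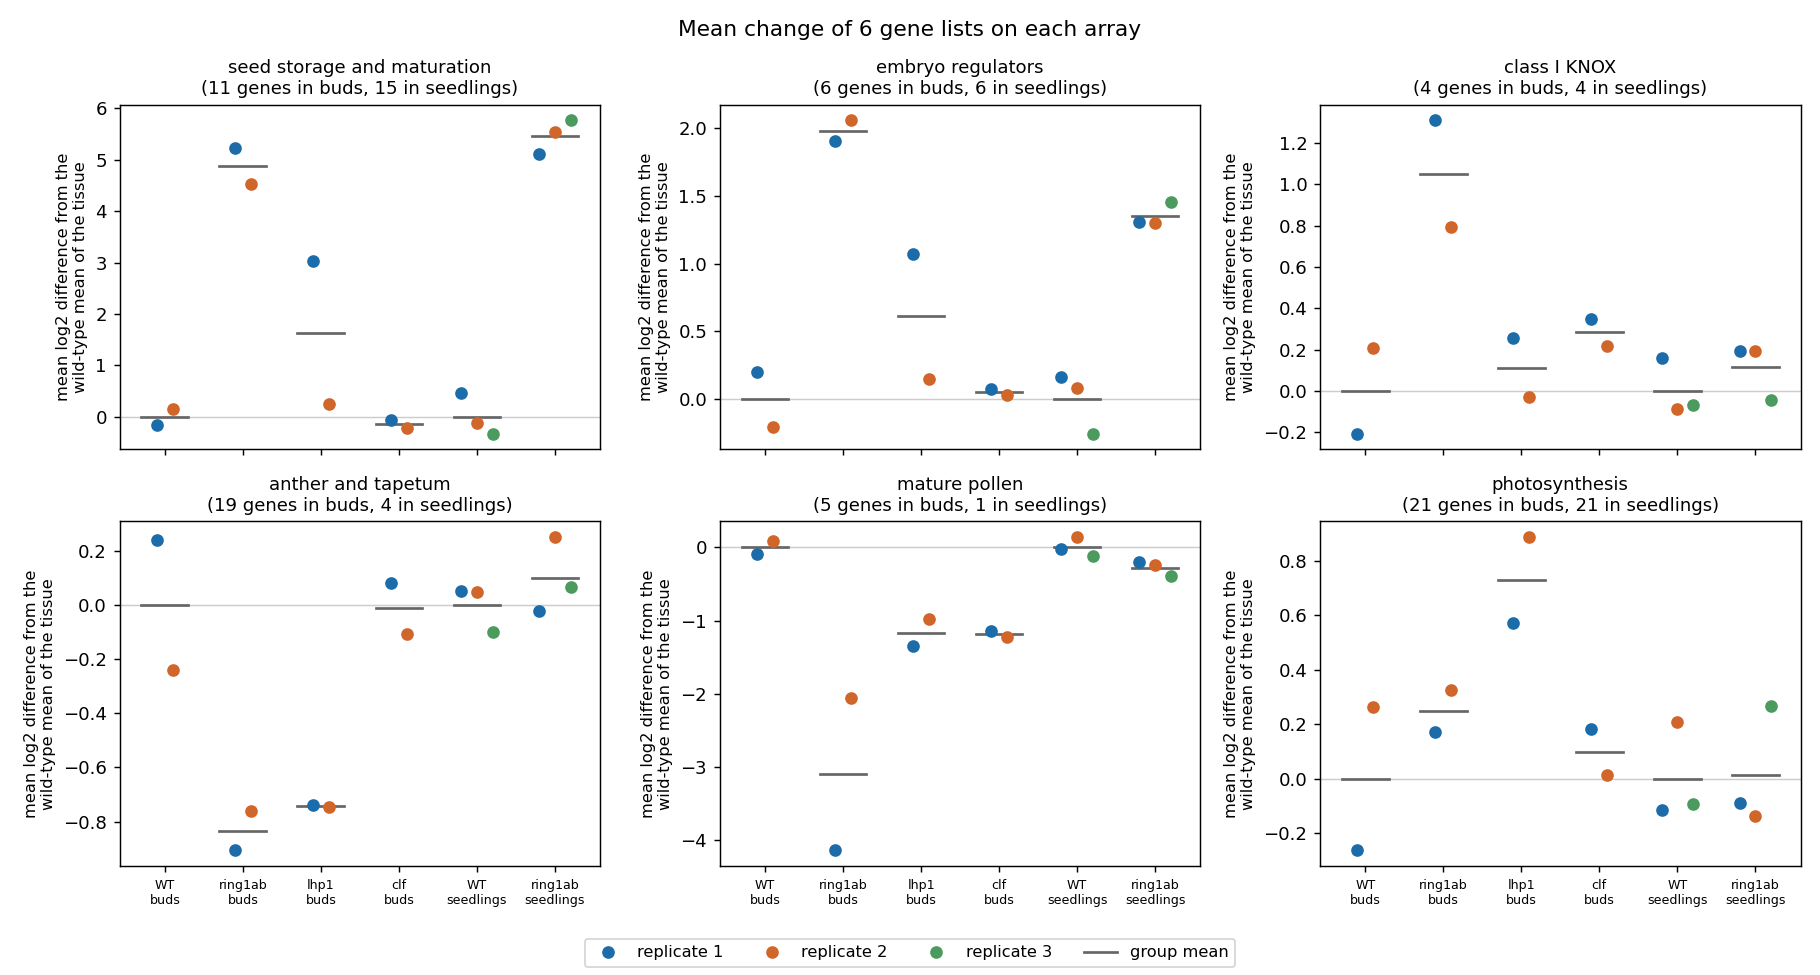
Mean log2 difference from the wild-type mean of the same tissue for 6 gene lists on each array; points are single arrays, coloured by replicate number, and bars are group means. The ring1ab arrays of both tissues lie above wild type for seed storage and maturation genes (group means 4.88 in buds and 5.47 in seedlings). For that list the array labelled lhp1 buds replicate 1 lies at 3.02 and lhp1 buds replicate 2 at 0.25. The ring1ab and lhp1 bud arrays lie below wild type for anther and tapetum genes (-0.83 and -0.74).

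In clf buds few genes differed from wild type. Besides CLF itself, CYP76C4, a cytochrome P450 gene, was at least 3.31-fold higher (log2 change 3.96 ± 0.24, adjusted p = 0.0352) and SK10, of the SKP1-like family, at least 3.10-fold higher (3.88 ± 0.25, adjusted p = 0.0352). SCRL21 was at least 1.12-fold lower (-2.33 ± 0.18, adjusted p = 0.0433). Other genes with large moderated statistics did not pass: log2 changes were 1.84 for PORA, 0.69 for WRKY54, -1.63 for DIN2 and -4.57 for MRD1, while PRX52 and Prx37 were at least 1.24-fold and 1.97-fold higher and PRSL1 and LCR64 at least 1.39-fold and 1.71-fold lower. The KNOX genes lay between 0.15 (STM) and 0.38 (KNAT1), with KNAT6 at 0.34 and KNAT2 at 0.26, and did not pass. RING1A (0.01), RING1B (-0.19) and LHP1 (0.10) did not pass either.

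The cell cycle and replication list lay higher in clf buds (mean 0.29, 0 of 13 called, adjusted p = 9.80e-05, and adjusted p = 0.774 with an estimated correlation), as did the defence list (0 of 6 called, mean 0.96 over the 5 members with values on every array, adjusted p = 0.00696, and adjusted p = 0.590 with an estimated correlation). With the stricter filter on dim probes the defence list kept 3 members and its call was lost (mean 0.53, adjusted p = 0.105). The mature pollen list lay lower (mean -1.19, 0 of 5 called, 1 adjusted over the list alone, adjusted p = 0.00522, and adjusted p = 0.590 with an estimated correlation). The mature pollen call was lost with the slide as a fixed block (mean -0.46, adjusted p = 0.228) and with the stricter filter (mean -1.19 over 4 members, adjusted p = 0.0579). Of 14 floral organ identity genes 1 rose adjusted over the list alone. Mean, median and test differed in sign for PRC2 components, floral organ identity, embryo regulators, seed storage and maturation, anther and tapetum, meiosis, auxin biosynthesis and reference genes. In all, 8 of 21351 genes differed, 2 higher and 6 lower, and 1740 had an unadjusted p under 0.05. The count was 1 and 2 without wild-type buds replicate 1 and 2, 322 and 301 without ring1ab buds replicate 1 and the library labelled replicate 2, and 0 without any of the lhp1 or clf arrays. Without both doubtful libraries it was 240, and MRD1, LCR64, DIN2 and PRSL1 were then called.

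The mutants were also set against each other in buds. Between ring1ab and lhp1 no gene passed (limma, lowest adjusted p = 0.0585, 6434 genes with an unadjusted p under 0.05). Among the largest differences that did not pass, log2 changes were 2.49 for CYP81F2 and 1.93 for OASA2 and M10 was at least 1.70-fold higher in ring1ab, while ACT4, PRA1.C and MEE8 were at least 1.5-fold, 1.2-fold and 2.07-fold lower. Without the library labelled ring1ab buds replicate 2 the count was 6414, without the library labelled lhp1 buds replicate 1 it was 536, and without ring1ab buds replicate 1 it was 8. Without both doubtful libraries 6260 genes differed, these 6 among them. Between ring1ab and clf 3327 genes differed, 1749 higher and 1578 lower in ring1ab. The balance depends on the fit: 52.6% were higher here, 84.7% with only the groups compared and 47.8% in 1 fit of all 14 arrays. EM1 (10.01 ± 2.31) was higher in ring1ab, AtLEA4-1 and PER1 at least 117-fold and 84.9-fold, while SK10 and CYP76C4 were at least 2.50-fold and 2.67-fold lower and TH7 lay at -3.41 ± 0.85. That count was 0 without either clf array, 1458 and 1580 without wild-type buds replicate 1 and 2, 1696 and 1745 without the library labelled lhp1 buds replicate 1 and replicate 2, 1703 without ring1ab buds replicate 1, 7942 without the library labelled ring1ab buds replicate 2, and 8158 without both doubtful libraries. Between lhp1 and clf 11 genes differed, 8 higher and 3 lower in lhp1. CLF was at least 32.3-fold higher in lhp1, GSTF2 (3.86 ± 0.23) and MYB48 (2.46 ± 0.12) were higher, SK10 and CYP76C4 were at least 2.51-fold and 2.68-fold lower, and YAB5 (-1.72) did not pass. That count ranged from 0 (without lhp1 buds replicate 2 or either clf array) over 5 (without either wild-type array) and 40 (without the library labelled lhp1 buds replicate 1) to 172 and 176 (without the library labelled ring1ab buds replicate 2 and replicate 1), and was 490 without both doubtful libraries.

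The calls of the bud mutants overlapped. Of the 144 genes that rose and 188 that fell in lhp1 buds, 126 and 179 were called in the same direction in ring1ab buds, against 15.9 and 25.3 for independent lists. Unchanged groups simulated against the same wild-type arrays shared 0.01 genes on average and at most 1. No gene differed in these draws, so few could be called and a count near 0 was set in advance. It is no baseline for mutants in which many genes are called. Across genes, log2 changes correlated at r = 0.660 with a covariance of 0.570, against r = 0.501 and a covariance of 0.0652 for the simulated unchanged groups. The difference of covariances was 0.505. A different wild-type array was then taken for each mutant, a test added after seeing the data. The covariance was 0.563 and 0.484 for the 2 ways to assign them, and 0.487 and 0.356 without the 2 doubtful libraries. Both wild-type bud arrays lay on slide 1, which held no mutant bud array. An offset of that slide would enter the changes of both mutants, so this test cannot separate genotype from slide. These libraries lie in both mutants: the shared count was 305 of the 332 lhp1 calls with them and 989 of 1643 without both. Of the 8 genes called in clf, 5 fell also in both ring1ab and lhp1 buds. These genes, listed here after their values were seen, were SCRL21, AT5G39365, AT1G14315, AT1G79915 and AT3G43110. Across genes, r was 0.529 (covariance 0.292) between clf and ring1ab and 0.543 (0.169) between clf and lhp1. With a different wild-type array for each mutant, r was 0.361 and 0.430 (0.231 and 0.260) between clf and ring1ab. Between clf and lhp1 it was 0.171 and 0.551 (0.0683 and 0.176), so the likeness of these 2 depends on the control taken. AT5G37320 and AT5G04047, also picked afterwards, were the 2 genes that fell in ring1ab and rose in lhp1. Removing an array moved the shared count of ring1ab and lhp1 to 0 (wild-type buds replicate 1), 3 (either clf array), 9 and 64 (lhp1 buds replicate 2 and the library labelled replicate 1), and 1795 and 1806 (ring1ab buds replicate 1 and the library labelled replicate 2). It moved those with clf to between 0 and 302.

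In ring1ab seedlings, compared with wild-type seedlings of the same age, the largest rises again included seed storage genes. Cruciferin C (CRC, AT4G28520), a seed storage globulin, rose by a log2 change of 8.65 ± 0.70 (adjusted p = 0.000644), and the other cruciferins CRA1 and CRU2 rose by 6.29 ± 0.52 and 7.05 ± 0.24, the latter at least 37.6-fold. The 2S albumin gene SESA3 rose by 7.28 ± 0.58, and SESA2 was at least 29.8-fold higher. Falls were smaller: CBL8, a calcium sensor (-2.13 ± 0.16), ATSDI1 (-1.78 ± 0.30), CASP5 of the Casparian strip family (-1.75 ± 0.15), PUP19 (at least 1.81-fold lower) and ChlAKR (-1.68 ± 0.27) were the largest beside RING1B.

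Of the 15 tested seed storage and maturation genes 14 rose (15 adjusted over the list alone), with a mean log2 change of 5.47 (adjusted p = 8.64e-27, and adjusted p = 0.0629 with an estimated correlation). Of the 15, 8 were above background on no wild-type seedling array, so the background enters this mean as well. The seedling fit held only wild type and ring1ab, so the filter takes in such genes through their ring1ab signal. This favours rises among the genes tested, as for L1L and SEP1 below. In the seed storage list it left no member out, since all 15 with a probe were tested. ATS1, a caleosin, was at least 17.0-fold higher and PAP85 rose by 4.14 ± 0.18. Of 6 embryo regulators 3 rose (4 adjusted over the list alone), namely ABI3 (3.03 ± 0.66), L1L (at least 2.69-fold) and WOX2 (1.11 ± 0.14). The adjusted p of that list was 4.58e-04, and 0.248 with an estimated correlation. WOX2 and WOX5 (0.93 ± 0.19) were the 2 of 7 WOX genes that rose (4 adjusted over the list alone, mean 0.53, adjusted p = 0.0472, and adjusted p = 0.359 with an estimated correlation). The 13 cell cycle and replication genes lay higher with none called (mean 0.36, adjusted p = 0.0472, and adjusted p = 0.967 with an estimated correlation). The WOX call was lost without wild-type seedlings replicate 1 (mean 0.56, adjusted p = 0.0604) or 3 (0.48, 0.0715) or ring1ab seedlings replicate 1 (0.52, 0.0710), and the cell cycle call without wild-type seedlings replicate 2 (0.24, 0.234) or 3 (0.24, 0.302) or ring1ab seedlings replicate 1 (0.25, 0.302). The WOX call was also lost with quantile normalization (0.46, 0.0653), normexp (0.35, 0.0732), the authors' values (0.45, 0.111), the mean of the probes (0.44, 0.161) and 1 fit of all 14 arrays (0.50, 0.0584), and the cell cycle call with normexp (0.28, 0.0598), no filter (0.36, 0.0743) and the slide as a random block (0.33, 0.281).

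In the fit reported here for seedlings none of the floral and flowering lists passed as a set, though single members did. With an estimated correlation, the floral organ identity list and the carpel and ovule list each had an adjusted p of 0.604. Of 14 floral organ identity genes with a probe 5 were tested, and of these 3 rose and 1 fell (adjusted p = 0.0553). The floral MADS genes SEP1 (at least 11.7-fold) and PI (1.64 ± 0.25) were higher and SEP4 (-0.67 ± 0.12) was lower. SEP1 was above background on no wild-type seedling array and entered the test through its ring1ab signal. Of 14 flowering time genes the FLC relatives MAF5 (2.25 ± 0.22) and MAF4 (1.66 ± 0.12) rose (2 rose and 1 fell adjusted over the list alone, adjusted p = 0.795), and of 6 carpel and ovule genes SPT (0.78 ± 0.16) and STY1 (at least 1.41-fold) rose (adjusted p = 0.0616). STY1 had the opposite sign with the mean of its probes (-0.44). The floral organ identity list passed with no filter (0.00137), 1 fit of all 14 arrays (9.01e-05), the slide as a random (2.20e-05) or fixed (0.000902) block, the scan session as a block (1.05e-05), and without wild-type (0.0255) or ring1ab (0.0442) seedlings replicate 2. The carpel and ovule list passed with no filter (0.0248), 1 fit of all 14 arrays (0.0281), the slide as a fixed block (0.000902), the replicate block (0.0362) and the scan session (0.0166), and without wild-type seedlings replicate 1 (0.0216) or 2 (0.0485) or ring1ab seedlings replicate 2 (0.0442). JAZ10 (-0.87 ± 0.13) fell among 6 jasmonate and wounding genes (1 rose and 1 fell adjusted over the list alone). Of 6 root hair genes 1 fell adjusted over the list alone. The KNOX genes did not pass, with log2 changes of 0.30 for STM, 0.22 for KNAT1, 0.17 for KNAT2 and -0.24 for KNAT6. CLF (0.19) and LHP1 (-0.13) did not pass either. Mean, median and test differed in sign for flowering time, leaf polarity and TCP, meiosis, photosynthesis and reference genes.

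In all, 825 of 18948 genes differed in ring1ab seedlings, 559 higher and 266 lower. The count was 472 and 410 without wild-type seedlings replicate 2 and 3, and 531, 298 and 434 without ring1ab seedlings replicate 1, 2 and 3; the 298 is also the value within the first scan session. With the slide as a fixed block in a fit of all 14 arrays 15 genes differed. The mean log2 change of the list seed storage and maturation in ring1ab seedlings was 6.29 there and kept its call (adjusted p = 6.03e-14). Replicate 2 of ring1ab seedlings, alone on its slide, did not enter the effect in that fit.

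Between tissues, 180 genes rose and 35 fell in both ring1ab buds and ring1ab seedlings, against 55.1 and 19.5 for independent lists. One-sided Fisher's exact tests gave p = 6.02e-51 and 4.99e-04, though genes are not independent replicates. The 2 comparisons share no array, but they share slides. Slide 1 held 2 wild-type arrays of each tissue, and slide 3 held 1 ring1ab bud and 2 ring1ab seedling arrays. The second scan session held only ring1ab arrays, 1 of each tissue. Slide and session may therefore add to the shared calls, and their part cannot be told apart from that of the genotype. Of the shared rises, those on the fixed lists were the seed genes CRU2, PAP85, EM1, OLEO1, ATS1, cruciferin C, OLEO2 and CRA1, with ABI3, WOX2, WOX5, SPT, STY1, MAF4, MAF5 and RING1A. A further 91 genes were called in opposite directions, for which no count for independent lists was computed. Log2 changes correlated at r = 0.248 across genes. The shared count of 215 was 18 and 67 without wild-type buds replicate 1 and 2, 131 without ring1ab buds replicate 1, 125 and 126 without clf buds replicate 1 and 2, and 113 without ring1ab seedlings replicate 2. It was 55 with only the groups compared and 6 with the slide as a fixed block.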

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

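The effect of the ring1ab genotype differed between seedlings and buds for 5285 genes (test of the interaction, limma, all 14 arrays). The log2 change in seedlings minus that in buds was positive for 3049 and negative for 2236. A positive sign can come from a fall in buds as well as from a rise in seedlings. Of the calls 57.7% were positive, against 46.4% with the stricter filter and 71.2% with the slide as a fixed block. The count was 3062 without wild-type buds replicate 1 and 3505 without ring1ab buds replicate 1. With the array labelled ring1ab buds replicate 2 left out it was 7000.

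Among named genes, the largest positive differences (seedlings minus buds) were in the albumin genes SESA4 and SESA3. SESA4 differed by 9.26 ± 1.48, with a log2 change of 6.11 in seedlings and -3.15 in buds. SESA3 differed by 7.34 ± 0.82, with 7.28 in seedlings, and was not above background on any wild-type or ring1ab bud array. LCR72, a defensin-like gene, followed with 7.19 ± 1.85, from log2 changes of 3.15 in seedlings and -4.04 in buds. The largest negative differences began with the embryogenesis gene EM6 (-7.61 ± 1.55, from 0.65 in seedlings and 8.27 in buds). AHL19 (-6.97 ± 1.36, from 0.07 and 7.04) and EDA32 (-6.05 ± 1.14, from 0.40 and 6.45) came next. In wild type, EM6 and AHL19 were above background on the 3 seedling arrays and on neither bud array. SESA4 was above background on 1 of the 2 ring1ab bud arrays, and LCR72 on 1 of these and on 2 of the 3 ring1ab seedling arrays. EDA32 was above background on neither wild-type bud array and on 1 of the 3 seedling arrays of each genotype. The sizes of all 6 differences therefore rest in part on signal at background.

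Probes that could not be assigned to a gene were left out of the comparisons, and some carried a signal that differed from wild type. They numbered 368 of 2875 in ring1ab buds (188 higher, 180 lower; 12.8%, against 24.5% of named genes) and 25 in lhp1 buds (11 higher, 14 lower). In clf buds 11 such probes were called (3 higher, 8 lower; 0.383%, against 0.0375% of named genes). In ring1ab seedlings 45 of 2230 were called (37 higher, 8 lower).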

How the results depend on the processing

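Of 17 counts, the slide as a fixed block moved 14 by more than 1.5 times and the stricter filter 10, the most among fits that kept all arrays. The cause was not tested for any change below, except that the stricter filter tests fewer genes, the minimum change of 2-fold removes called genes by construction, and leaving out arrays leaves fewer. Where 1 array of a group is left, it is assumed to vary like the other groups. For named genes and lists, the side of the threshold was the same in 2069 and 1296 of the checks that kept all arrays or left out the 2 doubtful ones. These include checks in which the sign changed while neither fit passed. A further 61 and 38 newly passed and 306 and 41 no longer did. With single arrays left out these numbers were 871 and 625, 28 and 23, and 353 and 11. The signal over background limits the folds of genes not above it, which are lower bounds. The fit without the 2 doubtful libraries (ring1ab buds replicate 2 and lhp1 buds replicate 1) and that with scan session were chosen after seeing the data. The 2-fold minimum was not run for lists, the estimated correlation only for lists, and 1 fit of all 14 arrays is already the one used for the 2 tissue comparisons.

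Reversed, counting only sign changes where the main or the other fit passed, was STY1 in ring1ab seedlings with the mean of its probes (-0.44). With the slide as a fixed block BMI1A (-0.15), VGD1 (0.12), BOP1 (0.090) and SPL (0.75) were reversed in ring1ab buds. None of these genes was past the threshold in these other fits. The slide block takes the ring1ab bud effect from the library labelled replicate 2 alone. The anther and tapetum list in clf buds, with arrays left out in turn, ranged from -0.25 to 0.23, and passed at both ends: at -0.25 without wild-type buds replicate 2 (adjusted p = 0.00367) and at 0.23 without replicate 1 (adjusted p = 0.0293). Against a main median log2 change of 0.02 over all genes in ring1ab buds, the authors' values gave 0.14, and for ring1ab against lhp1 buds 0.12 instead of -0.01. Of the genes called between lhp1 and clf buds 72.7% were higher in lhp1, and 85.5%, 83.7% and 84.5% with quantile normalization, normexp and the authors' values.

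Leaving out each array in turn gave between 463 and 8143 genes in ring1ab buds (5230 with all), 0 and 2532 in lhp1 buds (332), 0 and 322 in clf buds (8), 298 and 1021 in ring1ab seedlings (825), 0 and 6414 between ring1ab and lhp1 buds (0), 0 and 7942 between ring1ab and clf buds (3327), 0 and 176 between lhp1 and clf buds (11), 3062 and 7000 for the difference between tissues of the ring1ab effect (5285), and 13216 and 15964 between the wild-type tissues (15471). Lists ranged from 4 to 8 in ring1ab buds (4), 3 to 7 in lhp1 buds (4), 3 to 6 in clf buds (3) and 2 to 6 in ring1ab seedlings (4). Overlaps ranged from 0 to 1806 for ring1ab and lhp1 buds (305), 0 to 302 for ring1ab and clf buds and for lhp1 and clf buds (5 each), and 18 to 261 for ring1ab buds and seedlings (215). The list counts reached their ends without wild-type buds replicate 2 (8 in ring1ab and 6 in clf buds), lhp1 buds replicate 2 (7 in lhp1 buds), and wild-type seedlings replicate 3 or ring1ab seedlings replicate 1 (2 in seedlings).

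With the slide as a fixed block, genes numbered 191 in ring1ab buds, 20 in clf buds, 15 in ring1ab seedlings, 1 between ring1ab and lhp1, 352 between ring1ab and clf, 188 between lhp1 and clf, and 1824 for the difference between tissues. Lists numbered 7 in ring1ab buds, 6 in clf buds and 9 in ring1ab seedlings. Overlaps were 128, 17 (ring1ab and clf), 14 (lhp1 and clf) and 6 (buds and seedlings). With the slide as a random block genes numbered 50 in lhp1 buds, 1 in clf buds and 1691 in ring1ab seedlings, where the estimated correlation within slides was negative (-0.274), and overlaps were 46 for ring1ab and lhp1 buds and 0 for each with clf. With only the groups compared they numbered 337 in ring1ab, 868 in lhp1 and 491 in clf buds, 398 between ring1ab and clf and 994 between lhp1 and clf, with overlaps of 117, 52, 282 and 55 in the order above. With all 14 arrays in 1 fit they numbered 1721 in lhp1 and 55 in clf buds, 3151 between ring1ab and lhp1, 5559 between ring1ab and clf and 656 between lhp1 and clf, with overlaps of 1280, 44 and 43 among the bud mutants. With array weights they numbered 3329 in ring1ab, 1094 in lhp1 and 80 in clf buds, 1743 between ring1ab and clf and 272 between lhp1 and clf, with overlaps of 735, 61 and 65. With the intensity trend they numbered 199 in lhp1 and 1 in clf buds, with overlaps of 185, 0 and 0.

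With quantile normalization genes numbered 646 in lhp1 buds and 55 between lhp1 and clf, with overlaps of 568, 8 and 8. With normexp they numbered 691 in lhp1 and 0 in clf buds and 43 between lhp1 and clf, with overlaps of 592, 0 and 0 and 2 lists in ring1ab seedlings. The authors' values gave 2 between ring1ab and lhp1 and 58 between lhp1 and clf. With no filter on dim probes they numbered 210 in lhp1 buds, 1 in clf buds and 471 in ring1ab seedlings, with overlaps of 184, 0 and 0. With the stricter filter they numbered 0 in clf buds, 523 in ring1ab seedlings, 22 between lhp1 and clf and 3359 for the difference between tissues, with overlaps of 0 for each pair with clf and 84 rises and 21 falls (1.1e2 rounded) for buds and seedlings, and 2, 2 and 1 lists in ring1ab, lhp1 and clf buds. At a change of at least 2-fold they numbered 3349 in ring1ab buds, 414 in ring1ab seedlings, 2138 between ring1ab and clf and 9930 between wild-type tissues. With the inter-gene correlation estimated, 0 lists passed in each of the 4 main comparisons.

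With the 2 doubtful libraries left out genes numbered 8353 in ring1ab, 1643 in lhp1 and 240 in clf buds, 6260 between ring1ab and lhp1, 8158 between ring1ab and clf and 490 between lhp1 and clf, with overlaps of 989, 217 and 208. With scan session as a fixed block they numbered 2052 in lhp1 and 95 in clf buds, 545 between ring1ab and lhp1 and 794 between lhp1 and clf, with overlaps of 1450, 78, 80 and 140, and 7 lists in ring1ab seedlings. The counts that are not named for a setting stayed within 1.5 times the main ones.

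The replicate numbers did not pair the seedling samples: the deviations of same-numbered wild-type and ring1ab seedlings correlated at 0.0888, 0.00187 and -0.137, and not every array correlated best with its own number. In buds, with 2 replicates, same-numbered deviations correlated at -0.00598 for ring1ab with clf and between 0.0935 and 0.185 for the other pairs of groups. Arrays of different numbers then give the same values with the opposite sign. A weak pairing in buds is therefore not excluded. With the replicate number as a block, genes numbered 435 in ring1ab seedlings, 0 in clf buds and 18 between lhp1 and clf, the overlaps with clf were 0 and 0, and the other counts stayed within 1.5 times the main ones, such as 5250 in ring1ab buds and 306 in lhp1 buds.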

Other observations

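The 4 tests of the mixed arrays and the 3 tests of RING1A were chosen only after these results were seen.

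The wild-type tissues differed in 15471 of 22114 genes, 6794 higher in seedlings and 8677 higher in buds, with a median log2 change of -0.15 over all genes. The first principal component, with 81.9% of the variance, separated the tissues. Along it, both ring1ab bud arrays lay nearer to the seedlings than the other bud arrays (-69.8 and -114, against -177 and -170 in wild-type buds), while the ring1ab seedlings (168 to 182) lay close to wild-type seedlings (182 to 194). The lhp1 bud arrays lay at -126 and -127 and the clf bud arrays at -156 and -151.

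The arrays labelled ring1ab buds replicate 2 and lhp1 buds replicate 1 lay between the genotypes on the second component (60.9 and 6.48, against 162 in ring1ab buds replicate 1 and -29.8 in lhp1 buds replicate 2). A candidate explanation is that each array held RNA of both genotypes. Read from the mutated genes, LHP1 would put 16.1% ring1ab RNA on the array labelled lhp1 buds replicate 1, and RING1B would put 38.1% lhp1 RNA on that labelled ring1ab buds replicate 2. These shares predict a log2 ratio of -1.94 between the arrays for genes found in ring1ab only, and the 44 such genes with a level over -2 in ring1ab buds replicate 1 had a median of -1.82 with little spread (0.151 over the middle 50%), which this explanation needs. Set against ring1ab buds replicate 1, the shares predict -0.69 and -2.64 for the arrays labelled ring1ab buds replicate 2 and lhp1 buds replicate 1, and these genes had medians of -1.23 (standard error 0.0655) and -3.03, or 42.6% and 12.2% ring1ab RNA. Of the other kind, 137 genes were not above background on ring1ab buds replicate 1. They were above it on all wild-type and clf bud arrays and on lhp1 buds replicate 2, there at a level over -2. On the array labelled ring1ab buds replicate 2 their median was -1.26 (standard error 0.0298) against lhp1 buds replicate 2. Read as lhp1 RNA that is 41.8%, which leaves 58.2% and not 42.6%, but wild-type RNA would carry these genes too. RING1A lay at 0.21 on that array, close to 0.45 on ring1ab buds replicate 1 and far from -2.55 on lhp1 buds replicate 2. The shares themselves therefore stay open. RING1B kept a signal in ring1ab seedlings too, so its share rests on the assumption that ring1ab buds have none. A swap of the labels is argued against by LHP1, which lay below the arrays of other genotypes (-11.2 in their SD), and incomplete loss of LHP1 by RING1A, which lay above the other arrays without the ring1ab genotype (7.34 in their SD). Whether RNA, plants or labelled material were mixed stays open, and no biological explanation other than incomplete loss of LHP1 was tested.

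RING1A rose in ring1ab plants of both tissues, more in seedlings (7.61 on the log2 scale) than in buds (2.99). A rise shared by other genes of the complex is argued against by the 4 other tested PRC1 genes, whose median log2 change in seedlings was 0.0434 (standard error 0.122). A rise shared by the chromosomal neighbourhood is argued against as the whole cause: the 10 tested neighbours had a median of 0.06, under the RING1A change by 5.42 of their SD (1.39), though AT5G44310 rose by 4.14. A smaller shared rise of 1 log2 unit stays open, since the standard error of that median was 0.552. The position of the mutation relative to the probe was not tested, and a transcript that starts within or beyond the mutation may also give such a signal.

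In ring1ab buds the log2 changes correlated across genes with the difference between wild-type seedlings and clf buds, which shares no array with them (r = 0.486 over 21331 genes, which are not independent replicates). With ring1ab buds replicate 1 alone r was 0.478. After quantile normalization r was 0.501. The main scaling subtracts a constant from each array, which cannot change a correlation across genes, so this value does not test it as a cause. RNA of whole seedlings on the array of ring1ab buds replicate 1 is argued against as the whole cause. Of 71 genes bright in wild-type seedlings and not above background in wild-type and clf buds, 20 were above background there (28.2%, exact 95% interval 18.1% to 40.1%). By the choice of genes these 20 are a gain over wild-type and clf buds. A small share of seedling RNA, or RNA of leaf alone, stays open, since the genes were chosen in whole seedlings. A change in the tissue make-up or stage of the mutant buds, which the genotype may bring, stays open and was not tested. The same holds for the lower means of the anther and tapetum list in ring1ab and lhp1 buds. It also holds for those of the mature pollen list in ring1ab, lhp1 and clf buds.

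Of the 10 splits of the 6 seedling arrays into groups of 3, the real one gave 825 genes and the highest of the others 0; with 1 split as large in 10, the splits are too few for a share under 0.05.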
